A study of Bos indicus x Bos taurus with 45 samples.

How the data were processed

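Small RNA sequencing, which reads the short RNAs of a tissue and so counts microRNAs (miRNAs, small RNAs that repress target messenger RNAs), was done on tissues of bovine fetuses (Bos indicus crossed with Bos taurus) at about day 105 of gestation. Per the labels' protocols, total RNA was taken from frozen tissue with TRIzol, 2 µg per sample went into the Illumina TruSeq small RNA kit, and fragments of 140 to 160 bp were selected on a gel. The 45 libraries come in 4 tables, 1 per tissue: kidney (4 control, 4 LOS), liver (5 control, 4 LOS, 4 ART), skeletal muscle (4 control, 4 LOS) and tongue (9 control, 7 LOS, with the sex given). Control fetuses were conceived by artificial insemination. ART fetuses were of normal phenotype after assisted reproduction, and LOS fetuses had large offspring syndrome, a fetal overgrowth condition of ruminants seen after assisted reproduction.

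The deposited tables hold whole-number read counts per mature miRNA and library, not normalized, as made by the authors. Per the submitters' processing notes, Bowtie and the cattle build UMD3.1 were used in the 4 tissues and cutadapt 1.18 was named for tongue alone, with no role stated for any of them. The counting tool, the miRNA annotation and any filter on abundance are not given in the sources used here. The tables list 436 miRNAs in kidney, 563 in liver, 439 in skeletal muscle and 460 in tongue, and no listed count is 0. The lowest count in a table was 16 in kidney, 3 in liver, 6 in muscle and 8 in tongue, and the second-highest CPM of each listed miRNA was 5.22 or more. The tables thus hold the more abundant miRNAs, and their totals are totals of listed miRNAs, not full library depths. Some entries carry temporary names (33 in kidney, 63 in liver, 34 in muscle, 37 in tongue), and names ending in 3p or 5p mark the arm of the hairpin precursor a miRNA is cut from. Chromosome positions are not given because no miRNA annotation was used here. Each name occurred once per table, so the planned sum over copies of a name had nothing to sum and was not run. 4 pairs of entries had counts within 15% of each other in every library of the 4 tables, which can come from reads counted for both, and these entries (miR-1260b with miR-temp72-5p, miR-339a with miR-339b, miR-temp34-3p with miR-temp82-3p, and miR-temp81-5p with miR-temp94-3p) are uncertain.

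From these counts, CPM (the count of a miRNA relative to the total of listed reads of its library) and TMM scaling factors were computed in R 4.3.3 with edgeR 4.0.16. The factors lay between 0.943 and 1.07. The filterByExpr function of edgeR kept every listed miRNA. Each comparison was tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over all miRNAs of the table, with a call at an adjusted p under 0.05. Differences are log2 values with the standard error (SE) of the fit, and CPM values are means with the standard deviation (SD) between fetuses. In the comparisons CPM were scaled by the TMM factors, and in the tissue markers, the summed let-7 reads and values of single libraries they were not. The 3 liver groups shared 1 fit, tongue was fitted with a term for sex, and kidney and muscle were fitted alone. The difference in LOS effect between kidney, liver and skeletal muscle was an F test of the tissue by LOS interaction over 24 libraries of control 1 to 4 and LOS 1 to 4, with the fetus as a block, on the 389 miRNAs that these 3 tables share. The labels number the fetuses of each group and use the same numbers in each tissue, so a number was taken as 1 fetus. Separate dams, sires or processing days are not given for them, so p-values measure the spread between fetuses as labelled. Within a tissue, LOS 1 and control 1 are different fetuses, and the number does not pair them. Library pairs were compared for duplicates, and the closest pair within any group differed by a chi-square of 23.9 per degree of freedom or more.

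22 lists of miRNAs were fixed before the data were examined, as were the samples, the tests, the alternatives and the rule for named miRNAs. The lists cover cell types (skeletal muscle, hepatocyte, kidney and gut epithelium, general epithelium, squamous epithelium, red cell precursors, white blood cells, endothelium, smooth muscle and fibroblast, neuronal), imprinted loci (DLK1-DIO3, H19 and IGF2, PEG10 and MEST), families and clusters (let-7, miR-17 families, miR-15, miR-424 cluster, miR-34, miR-30, HOX cluster, ruminant miR-2284 and miR-2285) and hypoxia (miR-210). miR-192 and miR-194 stand in both the hepatocyte and the kidney and gut epithelium list. Both arms of a precursor count as separate members of a list where both are listed, so members are not independent. Lists with 3 or more members were tested against the other miRNAs with camera (limma 3.58.1, preset correlation of 0.01, log2 CPM with a prior count of 2) and adjusted over the lists of the comparison. camera with a correlation estimated from the data and fry, which tests the list alone, were run beside it. None of the camera calls below 0.05 within a tissue held with an estimated correlation. For each list the count of members that pass is given over all miRNAs and adjusted over the list alone. Named were the 10 miRNAs with the smallest p in each direction among those that passed (2 as values where none did), the 5 smallest p for sex and the interactions, the 2 most abundant members of each list, and miR-483, miR-675, miR-127, miR-122, miR-206, miR-451, miR-223 and miR-210. miR-675 was in none of the 4 tables.

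Agreement of LOS effects between tissues was a correlation across miRNAs of differences in log2(CPM + 1), for miRNAs of mean CPM 10 or more, with an exact permutation test that regroups the fetuses. Similarity of LOS and ART effects in liver was set against 100 simulations of unchanged groups that share the 5 controls. These simulations first drew around the observed control mean and were changed, after that result was seen, to draw all 13 libraries around 1 common mean. The spread within groups was the mean distance between libraries in log2(CPM + 1), with an exact permutation test (100000 resamples in tongue).

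The tests were checked on simulated counts with the means, depths and spread of the real libraries and known changes. In each comparison 200 miRNAs were changed at once, by 1.5-fold, 2-fold or 4-fold. For the tissue interaction the changes were placed in liver alone, and no effect shared by the tissues of a fetus was drawn. Of miRNAs changed 2-fold, 96.7% were recovered in kidney, 93.0% in liver LOS against control, 96.1% in liver ART against control, 91.7% in liver LOS against ART, 94.3% in muscle, 95.5% in tongue, 97.0% for sex, 84.6% for the sex by LOS term and 86.9% for the tissue interaction. For changes of 1.5-fold the shares were 81.2% in kidney, 84.8%, 75.9% and 75.5% in the liver comparisons in the same order, 65.0% in muscle, 88.7% in tongue, 90.3% for sex, 45.9% for sex by LOS and 49.4% for the tissue interaction. The simulation treats miRNAs as independent. With 200 changed miRNAs the adjusted threshold is looser than in the real comparisons, which had 0 to 15 calls. The shares can thus overstate what the real comparisons would recover. The alternatives fixed in advance were RLE and upper-quartile scaling, no filter, a mean CPM of at least 10, DESeq2 1.42.0, limma-voom, a robust fit, removal of the 3 most abundant miRNAs, other sample sets, a block on replicate number and leaving out each library in turn. Chosen after seeing the data were merging of the near-identical entries, leaving let-7 out of the scaling, the block in the list tests and the comparison of lists between tissues.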

Results

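miRNA profiles were compared between fetuses with large offspring syndrome (LOS) and controls in 4 tissues, to ask which miRNAs differ in this bovine overgrowth condition, which resembles Beckwith-Wiedemann syndrome of children. Liver also held fetuses of normal phenotype from assisted reproduction (ART), so that the conception method and the overgrowth could be compared apart. Listed reads per library ranged from 6132982 to 9170756 in kidney, 3379816 to 4976770 in liver, 4744968 to 6456252 in skeletal muscle and 9357833 to 13822348 in tongue. Groups overlapped in depth, for example 3379816 to 4134460 reads in liver controls, 3733598 to 4976770 in liver LOS and 3936697 to 4796102 in liver ART. 374 miRNAs were listed in all 4 tissues.

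The tissues had the marker miRNAs of their cell types. miR-122, the main miRNA of hepatocytes, stood at 18070 ± 1579 CPM (SD, n = 13) in liver, 8.38 ± 6.57 CPM (n = 8) in kidney and 12.5 ± 9.86 CPM (n = 8) in skeletal muscle, and was not listed in tongue. miR-133a, a miRNA of skeletal and heart muscle, stood at 14650 ± 1074 CPM in skeletal muscle and 15679 ± 1628 CPM (n = 16) in tongue against 34.5 CPM in kidney and 82.3 CPM in liver. miR-206, a skeletal muscle miRNA, was listed in muscle (750 ± 135 CPM) and tongue (652.9 ± 96.8 CPM). miR-192 was highest in liver (68920 ± 6353 CPM) and next in kidney (22246 ± 1484 CPM), and miR-205, of squamous epithelium, was highest in tongue (3074 ± 849 CPM). miR-451 of red cell precursors reached 13477 ± 725 CPM in liver, the blood-forming organ at this age, against 110 to 224 CPM in the other tissues. miR-10b alone made up 29.1% of listed reads in kidney, miR-411a 8.81% in liver, and miR-127, an imprinted miRNA of the DLK1-DIO3 domain, 10.6% in muscle and 13.3% in tongue.

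**Figure D1:**
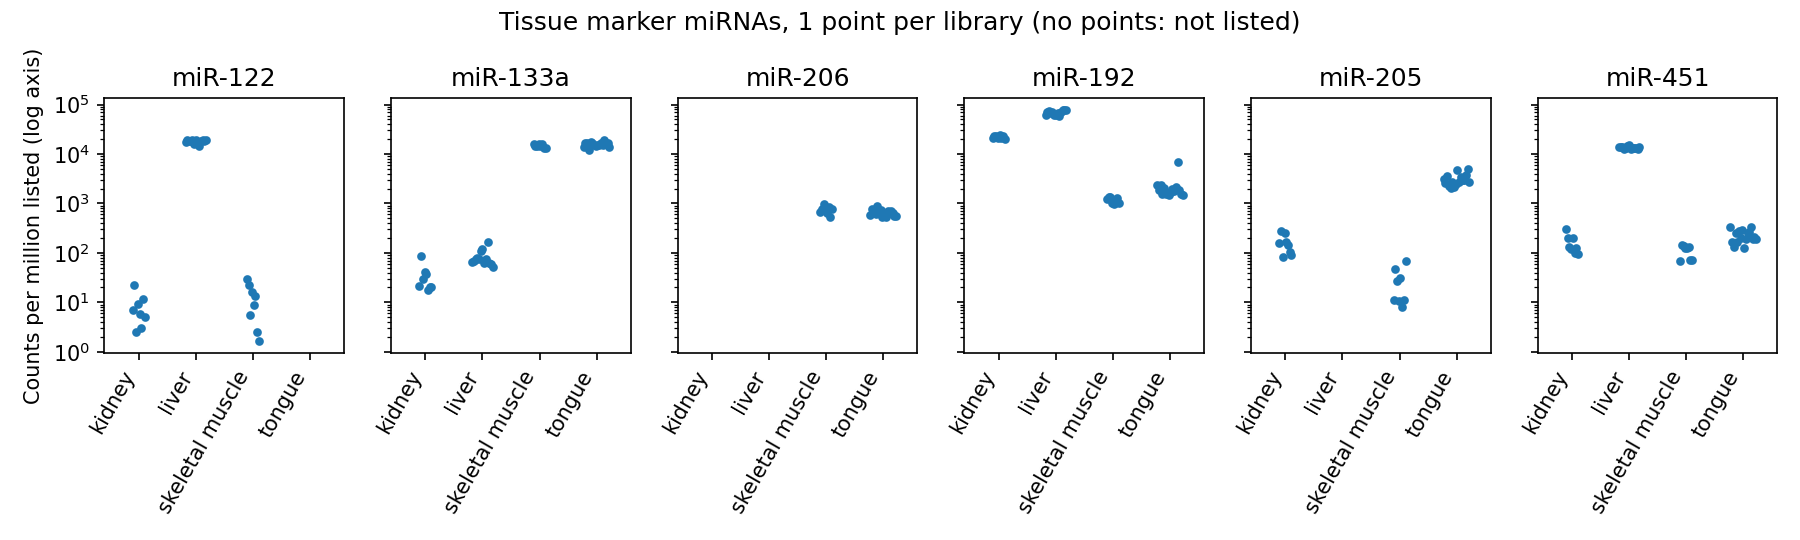
CPM of 6 marker miRNAs (log axis), with 1 point per library, in kidney, liver, skeletal muscle and tongue. miR-122 stands at 18070 CPM on average in liver, and miR-133a and miR-206 are highest in skeletal muscle and tongue.

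In liver, members of the let-7 family rose in LOS fetuses against controls conceived by artificial insemination. let-7 and miR-98 share a seed sequence, and the family is known for its increase as cells differentiate. let-7f went from 7811 ± 274 CPM (SD, n = 5) in controls to 11715 ± 1831 CPM (n = 4) in LOS, a log2 difference of 0.58 ± 0.08 (SE). let-7a-5p went from 4671 ± 219.1 to 6561 ± 769 CPM, a log2 difference of 0.49 ± 0.07. miR-98 (0.47 ± 0.07), let-7g (0.50 ± 0.08), let-7d (0.44 ± 0.08) and let-7i (0.36 ± 0.07) rose as well. In 4 of 4 LOS libraries let-7a-5p, let-7f, miR-98, let-7g and let-7d lay above every control, and let-7i did so in 3 of 4. miR-2408 fell by 2.78 on the log2 scale (SE 0.45), from 10.4 ± 4.78 to 1.53 ± 0.693 CPM, and lay below every control in 3 of 4 LOS libraries, since control 4 was itself at 2.07 CPM.

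These 7 miRNAs (6 higher, 1 lower) were the calls among 563 in edgeR's quasi-likelihood test, with adjusted p from 0.00243 for let-7a-5p and let-7f to 0.0270 for let-7i, and 79 miRNAs had an unadjusted p under 0.05. DESeq2 called 20 (9 higher, 11 lower), limma-voom 7, and RLE scaling gave 8 calls with 6 higher and 2 lower. Leaving out LOS 2 raised the count to 12 (9 higher, 3 lower). With the replicate number as a block, which does not pair the libraries, edgeR kept no call. That fit also left out control 5 and all ART libraries. let-7i lost its call without any of control 2, control 3, control 5, LOS 1, LOS 3 or LOS 4 (highest adjusted p in edgeR 0.122).

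**Figure D2:**
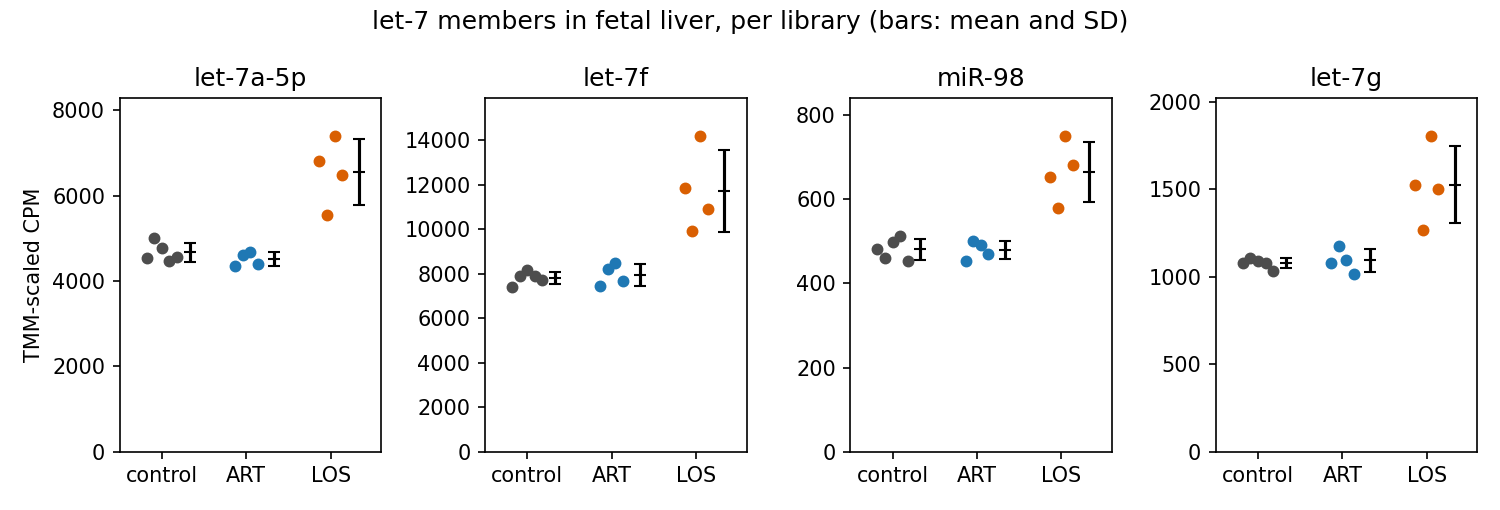
TMM-scaled CPM of let-7a-5p, let-7f, miR-98 and let-7g in each liver library, by group, with the mean and SD as a bar beside the points. Every LOS library lies above every control and ART library for these 4 miRNAs.

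By list, the let-7 members moved together in LOS liver. All 14 tested members were higher (median log2 difference 0.43), 6 rose over all miRNAs and 11 rose adjusted over the list alone, with a camera adjusted p of 2.35e-12. The list had an adjusted p = 0.193 with an estimated correlation and 0.0103 in fry. All 8 hepatocyte members were lower (median -0.15; camera adjusted p 0.00143, adjusted p = 0.231 with an estimated correlation), and 0 fell over all miRNAs while 2 fell adjusted over the list alone. miR-122 differed by -0.20 ± 0.06 (adjusted p 0.153 in edgeR, 0.0296 without LOS 2) and miR-192 by -0.13 ± 0.06. All 8 white blood cell members were lower (median -0.12; camera adjusted p 0.0121, adjusted p = 0.231 with an estimated correlation), with 0 calls and 0 adjusted over the list alone. Smooth muscle and fibroblast miRNAs were higher in 12 of 13 (median 0.18; camera adjusted p 0.00587, adjusted p = 0.326 with an estimated correlation), with 0 calls by either count, for example miR-143 at 0.18 ± 0.08 and miR-199a-3p at 0.44 ± 0.20.

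The miR-17 families, clusters with known roles in cell proliferation, were lower in 21 of 21 members in LOS liver (median -0.11; camera adjusted p 7.21e-05, adjusted p = 0.231 with an estimated correlation). 0 of them fell over all miRNAs and 3 fell adjusted over the list alone. miR-92a differed by -0.22 ± 0.06 (adjusted p 0.107 in edgeR, at lowest 0.0148 when LOS 3 or ART 1 was left out) and miR-25 by -0.14 ± 0.04. The miR-424 cluster, an X-linked cluster, was higher in 8 of 8 members (median 0.22; camera adjusted p 0.00659, adjusted p = 0.345 with an estimated correlation), with 0 calls and 1 that rose adjusted over the list alone. Kidney and gut epithelium miRNAs were lower in 4 of 5 (median -0.16; camera adjusted p 0.0397, adjusted p = 0.345 with an estimated correlation), with 0 calls by either count. Its camera call was lost without control 3 (adjusted p 0.0832), control 4 (0.0631), LOS 2 (0.152) or LOS 4 (0.153).

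Imprinted loci were of interest because loss of imprinting marks Beckwith-Wiedemann syndrome. In LOS liver the 84 DLK1-DIO3 members split into 47 higher and 37 lower, with a median of 0.01, a mean of -0.0041 and a camera direction of down (adjusted p 0.796). miR-127 of this domain differed by -0.21 ± 0.10. miR-483, from an intron of IGF2, was the only tested member of the H19 and IGF2 list and differed by 0.08 ± 0.12 (612 ± 110 CPM in controls, 647 ± 76.1 CPM in LOS). miR-335, hosted by MEST, differed by 0.47 ± 0.21 and its 3p arm by 0.49 ± 0.22. Neither of these passed over all miRNAs (lowest adjusted p 0.348 in edgeR). Both rose adjusted over the list alone, which holds only these 2 arms of the same precursor, so they are not independent.

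The other lists held 0 calls in LOS liver, over all miRNAs and adjusted over the list alone. Their medians were 0.20 for general epithelium (camera adjusted p 0.120), 0.02 for red cell precursors (0.860), 0.06 for endothelium (0.706), 0.12 for neuronal (0.528), 0.05 for miR-15 (0.120), 0.03 for miR-30 (0.930), 0.03 for the HOX cluster (0.796) and 0.32 for skeletal muscle (0.814). The 41 miR-2284 and miR-2285 members had a median of -0.05, a mean of 0.03 and a camera direction of down (0.930). miR-34, with 2 members, had a median of -0.09, and hypoxia-induced miR-210 differed by -0.13 ± 0.08.

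Liver of normal ART fetuses was compared with controls to ask what the conception method alone changed. let-7f stood at 7959 ± 493.9 CPM (SD, n = 4) in ART and 7811 ± 274 CPM (n = 5) in controls, a log2 difference of 0.03 ± 0.08 (SE), and let-7a-5p differed by -0.05 ± 0.07. The leading values were miR-temp32-5p (9.73 to 23.6 CPM, 1.28 ± 0.28) and miR-10164-3p (5.15 to 8.76 CPM, 0.76 ± 0.17), and below 0 miR-485-3p of the DLK1-DIO3 domain (421 to 343 CPM, -0.29 ± 0.08) and miR-18a-3p (-0.32 ± 0.10). By list, 20 of 21 miR-17 members were lower (median -0.05; camera adjusted p 0.000626, adjusted p = 0.819 with an estimated correlation). The miR-424 cluster was higher in 7 of 8 (median 0.23; camera adjusted p 0.0210, adjusted p = 0.819 with an estimated correlation), for example miR-450b at 0.27 ± 0.12. Neither list held a call over all miRNAs or adjusted over the list alone, 0 in each case.

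edgeR called 0 of 563 miRNAs between ART and control liver (lowest adjusted p 0.137), with 46 at an unadjusted p under 0.05. DESeq2 called 6 (5 higher, 1 lower) and limma-voom 0, and with only the ART and control libraries in the fit edgeR called 1, higher. Without control 5 edgeR called 5 (4 higher, 1 lower), and without ART 4 it called 1, miR-temp32-5p, at an adjusted p of 0.0208. The miR-424 camera call was lost without control 3 (adjusted p 0.0995), control 5 (0.0751), ART 1 (0.111) or ART 3 (0.183).

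Liver of LOS fetuses was set against normal ART fetuses to compare overgrowth among fetuses of assisted reproduction. let-7a-5p rose by 0.54 ± 0.07 (SE) on the log2 scale (4510 ± 161 CPM in ART, SD, n = 4; 6561 ± 769 CPM in LOS, n = 4), let-7f by 0.56 ± 0.09, miR-98 by 0.48 ± 0.08, let-7g by 0.48 ± 0.09, let-7d by 0.37 ± 0.09 and let-7f-1-3p, the other arm of a let-7f precursor, by 1.21 ± 0.28 (3.20 to 7.47 CPM). miR-192, a miRNA of liver and kidney epithelium, fell by 0.29 on the log2 scale (SE 0.06), from 76304 ± 4328 to 62418 ± 4215 CPM. miR-2408 fell by 2.84 (SE 0.46), and miR-2904 by 1.03 (SE 0.21), from 22.9 ± 5.04 to 11.2 ± 3.33 CPM. The other 6 that fell carry temporary names: miR-temp32-5p fell by 1.41, miR-temp91-5p fell by 0.87, miR-temp13-3p fell by 0.77, miR-temp34-3p fell by 0.61, miR-temp82-3p fell by 0.60 and miR-temp77-5p fell by 0.58. Each of the 6 let-7 calls lay above every ART library in 4 of 4 LOS libraries, and each of the 9 that fell lay below every ART library in 4 of 4. Of these 9, only miR-2408 was also called against controls. miR-temp32-5p was a leading value above 0 in ART against control liver, although it did not pass there. A fall against ART thus need not be a fall from the control level. miR-temp34-3p and miR-temp82-3p have near-identical counts and are uncertain as separate miRNAs.

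Of the let-7 list, 14 of 14 members were higher in LOS than in ART liver (median 0.49), 6 rose over all miRNAs and 12 rose adjusted over the list alone (camera adjusted p 3.21e-14, adjusted p = 0.128 with an estimated correlation, fry 0.00740). The hepatocyte list was lower in 7 of 8 members (median -0.18; camera adjusted p 0.00600, adjusted p = 0.609 with an estimated correlation), with 1 call, miR-192, and 4 that fell adjusted over the list alone. miR-122 differed by -0.23 ± 0.07 (adjusted p 0.101 in edgeR, 0.0177 without LOS 2), miR-194 by -0.26 ± 0.08 and miR-148a by -0.08 ± 0.07. miR-127 differed by -0.22 ± 0.10 and miR-483 by 0.12 ± 0.13, and neither passed.

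The 15 calls (6 higher, 9 lower) between LOS and ART liver had adjusted p from 0.00265 (let-7a-5p) to 0.0375 (miR-temp13-3p) in edgeR, with 87 miRNAs at an unadjusted p under 0.05. DESeq2 called 27 (10 higher, 17 lower) and limma-voom 15, and with only the LOS and ART libraries in the fit edgeR called 6 (3 higher, 3 lower). The count was 5 without LOS 1, 9 without LOS 3, 8 without ART 1 and 7 without ART 2. With the replicate number as a block, which does not pair the libraries, it was 3, in a fit that also left out all control libraries. Calls were lost for miR-temp34-3p and miR-temp82-3p without LOS 1 (adjusted p up to 0.0535), miR-temp77-5p without LOS 1, LOS 3, ART 1 or ART 2 (0.0624) and miR-2904 without LOS 1, ART 1 or ART 2 (0.0787). They were lost for miR-temp32-5p without LOS 1, LOS 3, ART 1, ART 2 or ART 3 (0.0801) and miR-192 without LOS 1, LOS 2, ART 2, ART 3 or ART 4 (0.0801). miR-temp91-5p lost its call without LOS 1, LOS 3, ART 1, ART 2 or ART 3 (0.0970), and miR-temp13-3p without control 3, control 4, LOS 1, LOS 2, LOS 3, ART 1, ART 2 or ART 3 (0.128). let-7f-1-3p and let-7d (both up to 0.117) lost theirs without LOS 1, LOS 3, LOS 4 or any ART library, and without control 2 or control 3, with control 4 added for let-7f-1-3p.

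The log2 differences of LOS and of ART liver from the same 5 controls correlated at r = 0.231 across 563 miRNAs, which are not independent replicates. Unchanged groups simulated against shared controls gave a mean r of 0.436 (0.241 to 0.590), and 100 of 100 simulations lay as high as the observed value. The covariance was 0.0156 against 0.0166 in the simulations, a difference of -0.00098, and 59 of 100 simulations lay as high. The simulations held no LOS or ART effect and drew each miRNA independently. An r below theirs thus does not show that LOS and ART effects are less alike than by chance. With separate controls for LOS and ART the mean r was 0.0171 (-0.0922 to 0.130 over 20 ways to divide them). Signs were shared by 59.7% of miRNAs, against 64.7% in the simulations.

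In kidney, miR-100 stood at 2548 ± 320 CPM (SD, n = 4) in controls and 1596 ± 415 CPM (n = 4) in LOS, a log2 difference of -0.68 ± 0.17 (SE), and lay below every control in 4 of 4 LOS libraries. miR-199a-5p, a mesenchymal miRNA, differed by -0.29 ± 0.07 (1496 ± 90.8 to 1221 ± 64.9 CPM). Above 0 the leading values were miR-708-3p at 0.36 ± 0.10 (229 ± 28.4 to 294 ± 15.2 CPM) and miR-34a, a miRNA induced by p53, at 0.73 ± 0.24 (5.95 to 9.91 CPM). None of these 4 passed (adjusted p 0.347 to 0.368 in edgeR). let-7f differed by -0.01 ± 0.06, miR-127 by -0.10 ± 0.08 and miR-483 by -0.18 ± 0.16. By list, smooth muscle and fibroblast miRNAs were lower in 10 of 12 (median -0.19; camera adjusted p 0.000279, adjusted p = 0.4931 with an estimated correlation, fry 0.256), with 0 calls over all miRNAs and 3 that fell adjusted over the list alone. In the miR-34 list 1 of 3 rose adjusted over the list alone. edgeR called 0 of 436 miRNAs, with 33 at an unadjusted p under 0.05, DESeq2 3 (all lower) and limma-voom 0. Without LOS 2 edgeR called 2, both lower, with miR-100 among them at an adjusted p of 0.0238.

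In skeletal muscle, miR-125b stood at 3398 ± 349 CPM (SD, n = 4) in controls and 2328 ± 205.8 CPM (n = 4) in LOS, a log2 difference of -0.55 ± 0.10 (SE). miR-296-3p, whose gene lies in the imprinted GNAS region, went from 311 ± 20.9 to 533 ± 114 CPM (0.78 ± 0.14), and miR-665, of the DLK1-DIO3 domain, from 1123 ± 67.1 to 1496 ± 59.6 CPM (0.41 ± 0.08). Each of the 3 separated LOS from control in all 8 libraries and had an adjusted p of 0.0526 in edgeR, just above the threshold. miR-199b differed by -0.51 ± 0.12 (adjusted p 0.180 in edgeR). miR-483, from an intron of IGF2, differed by 0.47 ± 0.13 (142.9 ± 12.3 to 198 ± 32.8 CPM; adjusted p 0.230 in edgeR) and rose adjusted over the list alone, as its only member. Muscle miRNAs did not pass, with miR-206 at -0.16 ± 0.15, miR-133a at -0.08 ± 0.07 and miR-133b at 0.13 ± 0.11, and 7 of the 9 members of that list lower.

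edgeR called 0 of 439 miRNAs in skeletal muscle, with 58 at an unadjusted p under 0.05, DESeq2 17 (10 higher, 7 lower) and limma-voom 0. RLE scaling, a mean CPM of at least 10 and removal of the 3 most abundant miRNAs each gave 3 calls (2 higher, 1 lower), and without LOS 3 edgeR called 1, miR-296-3p, at 0.0488. All 17 lists tested with camera had adjusted p between 0.505 and 0.588. Adjusted over the list alone, 1 DLK1-DIO3 member rose (miR-665) and 1 member each fell in the hepatocyte, kidney and gut epithelium, and smooth muscle and fibroblast lists.

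In tongue, where macroglossia is a sign of the syndrome, miR-10a stood at 652 ± 337.1 CPM (SD, n = 9) in controls and 369.3 ± 110 CPM (n = 7) in LOS, a log2 difference of -0.82 ± 0.27 (SE). It fell adjusted over the HOX cluster list alone, whose other member miR-10b differed by 0.01 ± 0.16. The smallest p values belonged to miR-2336 (11.8 ± 0.929 to 9.41 ± 0.883 CPM, -0.32 ± 0.08) and miR-484 (380.98 ± 20.9 to 333 ± 34.8 CPM, -0.20 ± 0.06), and above 0 to miR-2285q (0.35 ± 0.12) and miR-539 of the DLK1-DIO3 domain (0.28 ± 0.11). miR-206 differed by -0.14 ± 0.11, miR-133a by -0.05 ± 0.09, miR-205, the only tested member of the squamous epithelium list, by 0.21 ± 0.16 and let-7f by 0.01 ± 0.06. edgeR called 0 of 460 miRNAs (lowest adjusted p 0.481), with 25 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0.

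By list, kidney and gut epithelium miRNAs were lower in 3 of 4 in LOS tongue (median -0.63; camera adjusted p 0.0361, adjusted p = 0.883 with an estimated correlation), with 0 calls and 3 that fell adjusted over the list alone. miR-192 in this list differed by -0.64 ± 0.25 and miR-194 by -0.62 ± 0.21, and control 9 stood apart with 6810 CPM of miR-192 and 213.6 CPM of miR-194. Without control 9 miR-192 differed by -0.34 ± 0.08, miR-194 by -0.37 ± 0.09 and the list by a median of -0.35 (camera adjusted p 0.00336), with 2 that fell adjusted over the list alone. The hepatocyte list, which shares these, had 2 that fell adjusted over the list alone (camera adjusted p 0.195, and 0.0209 without control 9). miR-2284 and miR-2285 members were higher in 7 of 9 (median 0.21; camera adjusted p 0.0298, adjusted p = 0.883 with an estimated correlation), with 0 calls by either count. The first of these camera calls was lost without control 1 (adjusted p 0.0701), LOS 1 (0.103), LOS 2 (0.0862), LOS 4 (0.0924), LOS 5 (0.0866) or LOS 7 (0.0781). The other was lost without control 4 (0.166), LOS 4 (0.0924), control 7 (0.0877), LOS 6 (0.0552) or LOS 7 (0.0783).

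Male and female tongues (7 and 9 libraries) were compared with LOS status in the fit. miR-1185-3p of the DLK1-DIO3 domain differed by 0.52 ± 0.15 (SE, log2, male minus female) and miR-3432a-2-3p by 0.47 ± 0.13, while miR-10172-5p differed by -0.47 ± 0.14, miR-2478 by -0.26 ± 0.08 and mesenchymal miR-214 by -0.21 ± 0.06. None of them passed (adjusted p 0.313 in edgeR). The miR-2284 and miR-2285 list was higher in males in 9 of 9 members (median 0.28; camera adjusted p 0.00432, adjusted p = 0.956 with an estimated correlation, fry 0.585), with 0 calls by either count. edgeR called 0 of 460 miRNAs, with 62 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. For the difference of the LOS effect between males and females, the leading values were miR-temp66-3p at -2.97 ± 0.77, miR-temp26-5p at -1.93 ± 0.68, miR-temp54-5p at 1.38 ± 0.47, miR-temp97-5p at -1.19 ± 0.36 and miR-125b at 0.43 ± 0.16. edgeR called 0 of 460 (lowest adjusted p 0.658), with 20 at an unadjusted p under 0.05, DESeq2 and limma-voom 0, and no list passed. Without LOS 2 edgeR called 1, miR-temp66-3p, at an adjusted p of 0.0122.

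The LOS effect was compared between kidney, liver and skeletal muscle of the same 8 fetuses. let-7f differed between tissues (adjusted p of the interaction 0.0224 in edgeR), and in this joint fit its log2 LOS effect was higher in liver than in kidney by 0.55 ± 0.13 (SE) and than in muscle by 0.80 ± 0.13. let-7a-5p (0.48 ± 0.12 above kidney and 0.68 ± 0.12 above muscle; 0.0269), let-7g (0.41 ± 0.15 and 0.77 ± 0.15; 0.0363) and let-7d (0.41 ± 0.11 and 0.53 ± 0.11; 0.0414) differed in the same way. miR-296-3p had a higher LOS effect in muscle than in kidney by 0.44 ± 0.10, and in liver minus muscle a difference of -0.44 ± 0.10 (0.0363). These 5 were the calls among 389 miRNAs, with 73 at an unadjusted p under 0.05, and DESeq2 called 16 and limma-voom 6, while edgeR called 9 with a robust fit, 8 with the 3 most abundant miRNAs removed and 3 with tongue added. The count was 0 without each of control 1, control 2, control 3, control 4, LOS 1 and LOS 3, and 26 without LOS 2. All 5 lost their calls without each of the 6 fetuses named before LOS 2, and miR-296-3p, let-7g and let-7d also without LOS 4 (highest adjusted p 0.189).

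**Figure D3:**
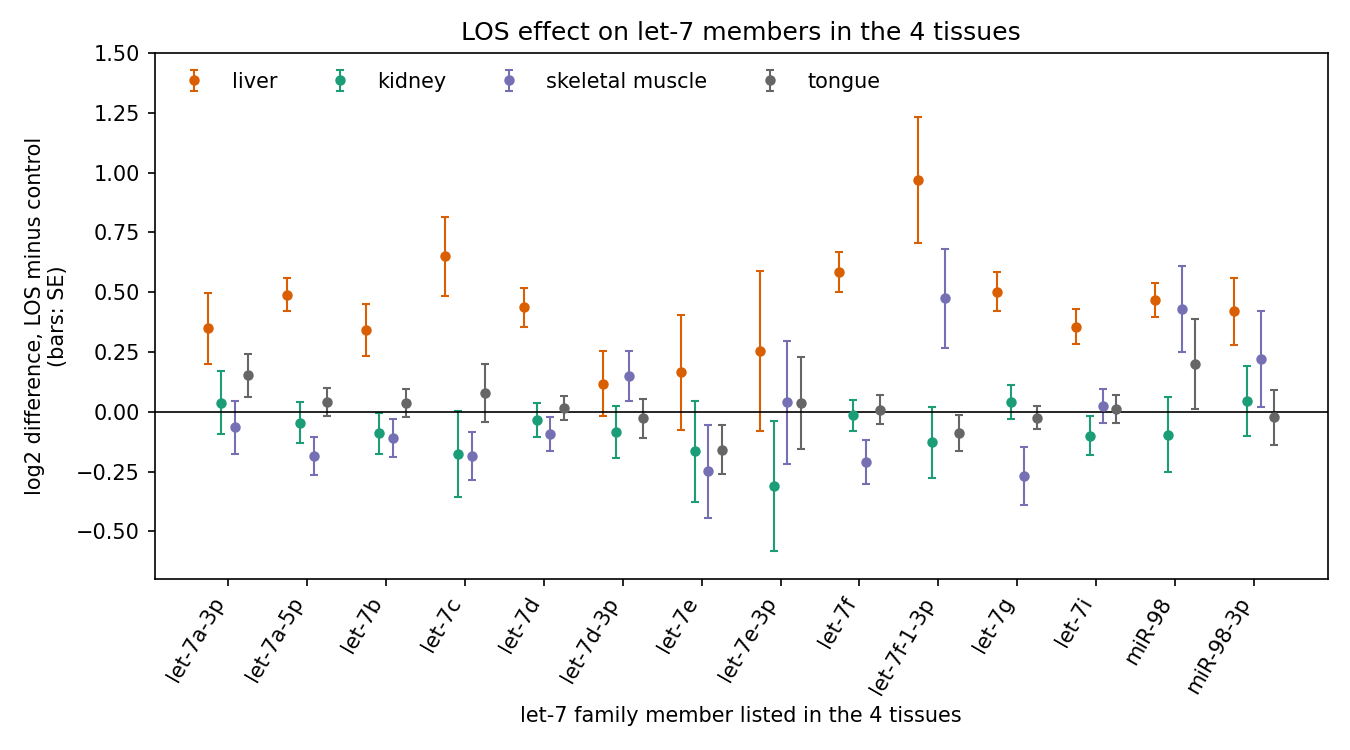
log2 differences (LOS minus control) of the let-7 family members listed in all 4 tissues, with the SE as bars, for liver, kidney, skeletal muscle and tongue, each from the fit of its own tissue with all of that tissue's libraries. let-7f lies at 0.58 in liver, -0.01 in kidney, -0.21 in skeletal muscle and 0.01 in tongue.

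LOS effects on all shared miRNAs were also correlated between tissues of the same fetuses, across miRNAs of mean CPM 10 or more, which are not independent replicates. Pearson's r was 0.369 for muscle and tongue (rho 0.309; exact one-sided p = 0.171 over 35 ways to regroup the 8 fetuses), 0.3302 for kidney and muscle (rho 0.245; exact p = 0.286) and 0.212 for kidney and tongue (rho 0.201; exact p = 0.571). It was 0.105 for liver and tongue (rho 0.0701; exact p = 0.429), 0.0858 for kidney and liver (rho 0.140; exact p = 0.771) and 0.0166 for liver and muscle (rho 0.0508; exact p = 0.914). After adjustment over the 6 pairs the exact p values were 0.857 to 0.914, and no pair passed. At a mean CPM of at least 100, r turned to -0.048 for liver and muscle and -0.052 for liver and tongue, and it was also below 0 without LOS 4 or control 4 for the first pair (-0.0826 and -0.0176) and without LOS 2 or LOS 4 for the second (-0.0107 and -0.00299). Without LOS 4 muscle and tongue had r = 0.494 (exact one-sided p = 0.0286), the highest value for this pair with single fetuses left out. That p is the smallest the test can give, and it was not adjusted over the fetuses and pairs tried.

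Distances between libraries within LOS and ART groups were set against those within controls, and no difference passed. The mean distance within LOS minus that within controls was 1.32 in liver (exact two-sided permutation p = 0.190), 1.36 in muscle (exact p = 0.343), 0.634 in kidney (exact p = 0.571) and 0.285 in tongue (permutation p = 0.797, 100000 resamples), and for ART in liver 1.10 (exact two-sided permutation p = 0.127). Adjusted over the 5 tests these p values were 0.476 to 0.797. The sign turned in kidney without LOS 3 (-0.337) or control 4 (-0.109), and in tongue with log2(CPM + 10) (-0.079), at a mean CPM of at least 100 (-0.373) and without LOS 3 (-0.0875) or control 2 (-0.0725).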

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

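The tests of explanations and of lists between tissues given here were chosen after the results were seen, except the test of summed let-7 reads and the median of the temporary-name entries in ART liver; the tissue interaction itself was planned.

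The LOS effect differed between kidney, liver and skeletal muscle for 5 miRNAs, with edgeR adjusted p of 0.0224 for let-7f, 0.0269 for let-7a-5p, 0.0363 for let-7g, 0.0363 for miR-296-3p and 0.0414 for let-7d. The count was 0 without each of control 1, control 2, control 3, control 4, LOS 1 and LOS 3, and 26 without LOS 2. As a list, let-7 had a higher LOS effect in liver than in kidney in 14 of 14 members (median difference 0.41, camera adjusted p 2.58e-14, adjusted p = 0.0185 with an estimated correlation, fry 0.00541). Its LOS effect was higher in liver than in muscle in 13 of 14 (median 0.39, camera adjusted p 2.93e-06, adjusted p = 0.300 with an estimated correlation, fry 0.00583). Smooth muscle and fibroblast miRNAs had a higher LOS effect in liver than in kidney (10 of 10, median 0.47, camera adjusted p 1.01e-08, adjusted p = 0.121 with an estimated correlation). Their LOS effect was also higher in liver than in muscle (8 of 10, median 0.43, camera adjusted p 0.0275, adjusted p = 0.581 with an estimated correlation). The miR-17 families had a lower LOS effect in liver than in kidney (median -0.14; camera adjusted p 0.0198, adjusted p = 0.742 with an estimated correlation), and the miR-424 cluster a higher one in liver than in muscle (8 of 8, median 0.35; 0.0103, adjusted p = 0.446 with an estimated correlation). Of the 35 ways to divide the 8 fetuses into 4 and 4, 2 gave 5 or more calls in the tissue interaction, the real one included, and the highest other gave 11, so chance was not excluded.

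The rise of let-7 in LOS liver made up 6 of the 7 calls against controls. Within each library the mean of the 14 let-7 members was taken relative to the median of the other 549 miRNAs, which no scaling factor can move. It was higher in LOS by 0.31 on the log2 scale (SD 0.228 in LOS and 0.0984 in controls, exact two-sided p = 0.0317), which argues against scaling. The summed let-7 reads went from 18329 ± 453.2 CPM (SD, n = 5) to 26159 ± 3054 CPM (n = 4), a log2 difference of 0.51 (edgeR adjusted p 0.00326), with ART at 18012 ± 571 CPM. All 14 members were already higher in LOS, which by itself argues against reads moved between members, so the sum had to rise. Both measures use the libraries that gave the calls and add no separate support for the rise. A lower share of hepatocytes (list score -0.13, exact two-sided p = 0.0556) would raise the other cell types alike. White blood cells instead stood at -0.15 (exact p = 0.00794). Red cell precursors were at 0.03 (exact p = 0.476), endothelium at 0.05 (exact p = 0.484) and general epithelium at 0.18 (exact p = 0.0635). Smooth muscle and fibroblast were at 0.26 (exact p = 0.0794). Only white blood cells had an exact p under 0.05, and differences between these scores were not tested. let-7 exceeded their mean by 0.33 (SD 0.220 in LOS and 0.0653 in controls, exact p = 0.0238). That argues against an even rise of these cell types as the whole cause. let-7 was not set against smooth muscle and fibroblast alone, so a higher share of mesenchymal or epithelial cells stays open. Only the real one of 100 drawn splits of the libraries gave 7 calls between LOS and control, and the highest other gave 6. Only the real one of 35 gave 15 between LOS and ART (highest other 3). Against controls not every possible split was drawn, and these shares were not adjusted over the comparisons split in this way. Chance is thus less likely but not excluded in either comparison, and 1 of 35 is the smallest share the splits against ART can give. A rise of let-7 with overgrowth is a hypothesis beside these cell shares, liver maturity, processing order and cell types outside the lists, which stay open, whereas the tongue labels give control 1 to 5 and LOS 1 to 4 as female, so fetal sex did not differ against controls if a number is 1 fetus, and the sex of ART fetuses is not given in the labels.

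The loss of miR-2408 in LOS liver rests on few reads (6, 5, 11 and 5 in LOS; 46, 44, 55, 7 and 50 in controls; 55, 54, 42 and 37 in ART). The summed 27 reads in LOS lie below the 165 that counting noise alone allows around 191 at the control and ART rate. The edgeR call that picked miR-2408 already allowed for counting noise, so this count adds no separate support. The range also leaves out differences between fetuses, such as the 7 reads of control 4. A variant carried by single fetuses could give the same pattern, since control 4, at 2.07 CPM, is as low as LOS and the other controls are at 11.6 to 14.2 CPM. That cannot be told apart from an effect of LOS, because 0 of the other 3 tables list miR-2408, so the same fetuses could not be read in another tissue. An effect of LOS stays open as well, untested.

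Entries with temporary names made up 6 of the 9 miRNAs lower in LOS than in ART liver, and the 63 such entries as a set were lower in 49 (median -0.23; camera adjusted p 1.03e-07, adjusted p = 0.196 with an estimated correlation). In 14 of the 15 pairs of these 6 entries the ratio of counts varied over the 13 liver libraries beyond counting noise (chi-square, adjusted p under 0.05), all but miR-temp34-3p with miR-temp82-3p, which argues against the same reads counted in each entry as the whole pattern. If ART libraries held more fragments of other RNAs, which such entries may come from, the set would be higher in ART than in control liver, and it was by a median of 0.17 (43 of 63 higher; camera adjusted p 0.000391, adjusted p = 0.367 with an estimated correlation). That lies between the limits of 0.1 and 0.2 set beforehand. Fragments and an effect of conception method could both give such a rise, so this median cannot tell them apart at any height. An effect of the group stays open and untested.

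Single libraries stood apart from their group in 13 of 222 groups of values tested, and chance marks about 1 in 20 groups, or 11.1 here. In liver, miR-223 was 147.5 CPM in control 5 (others 105 to 115), miR-122-3p 1009 CPM in LOS 2 (931 to 943), miR-133a 169 CPM in ART 1 (52.8 to 63.1) and miR-2408 2.07 CPM in control 4. In kidney, miR-483 was 93.7 CPM in LOS 4 (153 to 158) and miR-133a 37.7 CPM in LOS 1 (17.7 to 20.8). In skeletal muscle, miR-127 was 125684 CPM in control 1 (97602 to 102242), whose 3 most abundant miRNAs took 33.3% of reads (29.2 to 29.5%), while miR-665 was 1603 CPM in LOS 2 (1439 to 1449) and miR-210 114 CPM in control 2 (97.4 to 100.1). In tongue, miR-192 was 6810 CPM (1549 to 2406) and miR-194 213.6 CPM (54.6 to 90.2) in control 9, and the 3 most abundant miRNAs took 33.8% of reads in control 4 (28.4 to 30.6%).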

How the results depend on the processing

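Merging of near-identical entries, leaving let-7 out of the scaling and the block in the list tests were chosen after seeing the data; the other settings were planned. Of the values of named miRNAs under an alternative, 3793 kept their direction and side of the threshold, 29 came to pass, 47 no longer passed and the rest, each given here, changed sign, and for lists 225 kept their side and 48 no longer passed. The planned sum over copies of a name was not run, as no name had copies. With DESeq2 the calls were 3 in kidney, 20 and 6 in liver LOS and ART against control, 27 in liver LOS against ART, 17 in muscle and 16 in the tissue interaction. Liver ART against control gave 1 call and liver LOS against ART 6 with only the groups compared. Muscle gave 3 calls each with RLE scaling, a mean CPM of at least 10 and the 3 most abundant removed. The tissue interaction gave 9 with a robust fit, 8 with the 3 most abundant removed and 3 with tongue added. Lists that passed were 0 in each comparison within a tissue with an estimated correlation, and with fry 1 in liver LOS against control, 1 against ART and 0 in kidney, liver ART against control, tongue and tongue sex. In kidney 5 lists passed with a mean CPM of at least 10. Between tissues, r was -0.048 for liver and muscle and -0.052 for liver and tongue with a mean CPM of at least 100. The tongue spread was -0.079 with log2(CPM + 10) and -0.373 with a mean CPM of at least 100. With controls split, r of LOS and ART effects was 0.0171, since shared controls add to it. The cause of the other changes was not tested.

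Without single libraries, calls ran from 0 to 2 in kidney (2 without LOS 2) and 6 to 12 in liver LOS against control (12 without LOS 2). Counts ran from 0 to 5 in liver ART against control (1 without ART 4, 5 without control 5) and 5 to 20 in liver LOS against ART (5 without LOS 1, 7 without ART 2, 8 without ART 1, 9 without LOS 3). Counts ran from 0 to 1 in skeletal muscle (1 without LOS 3) and 0 to 1 for tongue sex by LOS (1 without LOS 2). Counts ran from 0 to 26 in the tissue interaction (0 without any control, LOS 1 or LOS 3, 26 without LOS 2). Lists that passed ran from 1 to 4 in kidney (2 without control 2, LOS 2 or LOS 4, 3 without control 1, 4 without LOS 3) and 1 to 2 in liver ART against control (1 without control 3, control 5, ART 1 or ART 3). Passing lists ran from 2 to 5 in liver LOS against ART (4 without LOS 1, 5 without ART 1) and 0 to 3 in tongue (0 without LOS 4 or LOS 7, 1 without control 1, control 7, LOS 1, LOS 2 or LOS 5). Passing lists ran from 0 to 3 for tongue sex by LOS (1 without control 4, control 8, LOS 4 or LOS 5, 3 without control 5, LOS 3 or LOS 6). Between tissues r ran from -0.0826 to 0.11 for liver and muscle (-0.0826 without LOS 4, -0.0176 without control 4), -0.0107 to 0.304 for liver and tongue (-0.0107 without LOS 2, -0.00299 without LOS 4) and 0.234 to 0.494 for muscle and tongue (0.494 without LOS 4). Spread differences ran from -0.337 to 1.35 in kidney (-0.337 without LOS 3, -0.109 without control 4) and -0.0875 to 0.817 in tongue (-0.0875 without LOS 3, -0.0725 without control 2). Depth limits most the entries near the lowest listed CPM, such as miR-2408, and miRNAs below the listing limit were not analysed here.

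With the replicate number as a block (replicate block), liver LOS against control gave 0 calls, ART against control 1 and LOS against ART 3, and lists that passed were 1 in liver ART against control, 4 in LOS against ART and 5 in tongue. The block fits of single miRNAs held only the groups compared and the numbers present in both, so the libraries changed along with the block. The numbers do not pair the libraries: same-numbered deviations correlated over 0.1 in 0 of 4 pairs in kidney, 1 of 4 in liver LOS and control, 1 of 4 in LOS and ART, 3 of 4 in ART and control, 1 of 4 in muscle and 3 of 7 in tongue (lowest r -0.491, highest 0.383), and not every library correlated best with its own number in any of them. miR-342 gave 0.0020 and miR-2284x -0.019 with the replicate block in liver LOS against control. miR-429 gave -0.012 and miR-143 -0.020 with the replicate block in liver ART against control. miR-10a gave -0.0028 with the replicate block in liver LOS against ART. miR-210 gave -0.028, miR-133a 0.019, miR-141 -0.074, miR-142-5p 0.068, miR-182 -0.10 and let-7f -0.033 with the replicate block in tongue. miR-16b gave -0.10, miR-16a -0.015, miR-542-3p 0.035, miR-34a -0.0094 and miR-30e-5p 0.012 with the replicate block in tongue.

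Signs that changed under other settings, all of log2 differences that did not pass as reported: miR-126-3p gave 0.0011 with RLE scaling in kidney. miR-127-5p gave -0.036, miR-182 -0.043, miR-335 -0.023, miR-92a -0.028 and miR-424-5p -0.018 with upper-quartile scaling in kidney. miR-450b gave -0.0024, miR-30d -0.0045, miR-2284x -0.018 and miR-2284w-3p -0.055 with upper-quartile scaling in kidney. miR-182 gave -0.0059 and miR-2284w-3p -0.015 with a mean CPM of at least 10 in kidney. miR-126-3p gave 0.0011 with DESeq2 in kidney. miR-126-3p gave -0.0032 and miR-2284x -0.0027 with near-identical entries merged in liver LOS against control. miR-126-3p gave -0.010 and miR-2284x -0.0098 with only the groups compared in liver LOS against control. miR-34c gave -0.00031 with RLE scaling in liver ART against control. miR-148a gave -0.011, miR-34c -0.0046 and miR-10a -0.015 with upper-quartile scaling in liver ART against control. miR-34c gave -0.00071 with DESeq2 in liver ART against control. miR-199a-3p gave 0.0090 and miR-34c -0.0035 with limma-voom in liver ART against control. miR-34c gave -0.0016 and miR-10a -0.0016 with the 3 most abundant removed in liver ART against control. miR-127-5p gave 0.011 with upper-quartile scaling in liver LOS against ART. miR-127-5p gave 0.00034 and miR-10a -0.00015 with limma-voom in liver LOS against ART. miR-223 gave -0.0027 with near-identical entries merged in liver LOS against ART. miR-335-3p gave 0.010 and miR-449a 0.0066 with RLE scaling in skeletal muscle. miR-449a gave 0.012 with upper-quartile scaling in skeletal muscle. miR-335-3p gave 0.0016 and miR-449a 0.00023 with a mean CPM of at least 10 in skeletal muscle. miR-335-3p gave 0.010 with DESeq2 in skeletal muscle. miR-335-3p gave 0.0065 and miR-449a 0.0040 with the 3 most abundant removed in skeletal muscle. miR-335-3p gave 0.021 and miR-449a 0.015 with near-identical entries merged in skeletal muscle. miR-200a gave 0.016, miR-142-5p 0.042, miR-143 0.048 and miR-199a-3p 0.041 with upper-quartile scaling in tongue. miR-92a gave 0.039, miR-542-3p 0.048 and miR-30e-5p 0.023 with upper-quartile scaling in tongue. miR-143 gave 0.0021, miR-199a-3p 0.00035, miR-92a 0.00092 and miR-542-3p 0.0056 with a mean CPM of at least 10 in tongue. miR-128 gave -0.00054 with the 3 most abundant removed in tongue. miR-128 gave -0.0027 with no sex term in tongue. miR-451 gave 0.12, miR-133a 0.021, miR-148a -0.086, miR-204 -0.094, miR-141 -0.090 and miR-143 0.037 with females only in tongue. miR-182 gave -0.20, let-7f -0.0059, miR-92a 0.017, miR-16b -0.073, miR-542-3p 0.072 and miR-10b -0.0065 with females only in tongue. miR-483 gave -0.043, miR-133b -0.26, miR-200a 0.046, miR-142-5p 0.11 and miR-126-5p -0.024 with males only in tongue. miR-126-3p gave -0.030, miR-199a-3p 0.056, miR-128 -0.019 and let-7i -0.073 with males only in tongue. miR-206 gave 0.023, miR-451 0.059, miR-133a 0.092, miR-148a -0.10, miR-204 -0.19 and miR-141 -0.22 with fetuses 1 to 4 only in tongue. miR-486 gave 0.016, miR-143 0.052, miR-182 -0.29, miR-92a 0.050, miR-16b -0.10 and miR-16a -0.016 with fetuses 1 to 4 only in tongue. miR-542-3p gave 0.12, miR-34c -0.018, miR-30e-5p 0.0099 and miR-10b -0.016 with fetuses 1 to 4 only in tongue.

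Leaving out single libraries moved some log2 differences across 0. miR-122 ran from -1.18 to 0.0099, miR-127-5p from -0.050 to 0.14, miR-192 from -0.050 to 0.048 and miR-486 from -0.071 to 0.16 in kidney. miR-155 ran from -0.064 to 0.12, miR-126-3p from -0.10 to 0.058, miR-182 from -0.062 to 0.10 and miR-411a from -0.11 to 0.11 in kidney. miR-335 ran from -0.11 to 0.12, let-7f from -0.048 to 0.021, let-7a-5p from -0.10 to 0.034 and miR-92a from -0.012 to 0.065 in kidney. miR-424-5p ran from -0.026 to 0.15, miR-450b from -0.022 to 0.13, miR-449a from -0.15 to 0.29 and miR-10a from -0.10 to 0.00052 in kidney. miR-2284w-3p ran from -0.041 to 0.068 in kidney. miR-451 ran from -0.016 to 0.059, miR-483 from -0.0032 to 0.16, miR-342 from -0.058 to 0.0029 and miR-126-3p from -0.045 to 0.071 in liver LOS against control. miR-409a-3p ran from -0.016 to 0.071, miR-16b from -0.0064 to 0.055, miR-16a from -0.000049 to 0.042 and miR-10a from -0.11 to 0.11 in liver LOS against control. miR-2284x ran from -0.019 to 0.022 and miR-2284w-3p from -0.10 to 0.012 in liver LOS against control. miR-122-3p ran from -0.045 to 0.023, miR-127 from -0.044 to 0.10, miR-451 from -0.044 to 0.0011 and miR-483 from -0.12 to 0.036 in liver ART against control. miR-133a ran from -0.30 to 0.44, miR-148a from -0.037 to 0.045, miR-429 from -0.10 to 0.068 and miR-200a from -0.18 to 0.0022 in liver ART against control. miR-486 ran from -0.072 to 0.0032, miR-126-5p from -0.024 to 0.047, miR-126-3p from -0.0020 to 0.11 and miR-143 from -0.037 to 0.064 in liver ART against control. miR-199a-3p ran from -0.14 to 0.079, miR-128 from -0.048 to 0.082, miR-182 from -0.31 to 0.058 and miR-411a from -0.047 to 0.0060 in liver ART against control. miR-335 ran from -0.13 to 0.067, miR-335-3p from -0.054 to 0.13, let-7f from -0.0064 to 0.048 and miR-16b from -0.047 to 0.0090 in liver ART against control. miR-34c ran from -0.091 to 0.058, miR-30e-5p from -0.048 to 0.024, miR-10a from -0.037 to 0.084 and miR-10b from -0.23 to 0.54 in liver ART against control. miR-127-5p ran from -0.039 to 0.030, miR-210 from -0.11 to 0.0077, miR-223 from -0.059 to 0.084 and miR-133a from -0.12 to 0.61 in liver LOS against ART. miR-499 ran from -0.21 to 0.13, miR-126-3p from -0.10 to 0.0088 and miR-10a from -0.11 to 0.086 in liver LOS against ART. miR-127-5p ran from -0.075 to 0.0075, miR-127 from -0.022 to 0.12, miR-141 from -0.28 to 0.68 and miR-205 from -0.53 to 0.90 in skeletal muscle. miR-9 ran from -0.86 to 0.57, miR-335-3p from -0.088 to 0.092, let-7i from -0.020 to 0.078 and miR-16a from -0.062 to 0.34 in skeletal muscle. miR-449a ran from -0.39 to 0.27, miR-30d from -0.10 to 0.021 and miR-10a from -0.18 to 0.053 in skeletal muscle. miR-483 ran from -0.012 to 0.12, miR-133b from -0.035 to 0.10, miR-148a from -0.087 to 0.13 and miR-141 from -0.0052 to 0.16 in tongue. miR-200a ran from -0.13 to 0.061, miR-142-5p from -0.10 to 0.081, miR-126-5p from -0.024 to 0.045 and miR-126-3p from -0.024 to 0.16 in tongue. miR-143 ran from -0.073 to 0.046, miR-199a-3p from -0.045 to 0.014, miR-182 from -0.059 to 0.18 and miR-128 from -0.079 to 0.046 in tongue. let-7f ran from -0.025 to 0.033, let-7i from -0.014 to 0.049, miR-92a from -0.048 to 0.037 and miR-16b from -0.034 to 0.050 in tongue. miR-16a ran from -0.016 to 0.080, miR-542-3p from -0.038 to 0.034 and miR-10b from -0.093 to 0.10 in tongue.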

Other observations

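The tests of shared deviations and of other splits given here were chosen after the results were seen.

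miR-296-3p, whose gene lies in the imprinted GNAS region, had a positive log2 difference between LOS and control in the separate fits of 3 tissues, 0.78 ± 0.14 (SE) in skeletal muscle, 0.34 ± 0.12 in liver and 0.29 ± 0.16 in kidney, and passed in none of them alone. The temporary-name entries as a set were also higher in LOS than in control muscle (median 0.15; camera adjusted p 0.00868, adjusted p = 0.367 with an estimated correlation) and lower in LOS than in control liver (median -0.11; 0.00442, adjusted p = 0.367 with an estimated correlation), with values of 0.12 in kidney (0.116) and 0.03 in tongue (0.843).

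A fetus-wide deviation was tested as a hypothesis: where a fetus departs from its group in 1 tissue, it may depart alike in another. The mean correlation of same-fetus deviations across miRNAs was 0.221 for liver and muscle (exact one-sided p = 0.00347), 0.211 for kidney and tongue (exact p = 0.00868), 0.172 for muscle and tongue (exact p = 0.0104), 0.217 for kidney and muscle (exact p = 0.0122) and 0.162 for kidney and liver (exact p = 0.0139), over 576 arrangements of the 8 fetuses. Other fetuses gave -0.028 to -0.076. Deviations from a group cancel within it, so these values fall below 0 where same-fetus values lie above 0, and they add no separate support. After adjustment over the 6 tissue pairs, 5 passed (adjusted exact p = 0.0167), and liver and tongue (0.0603; exact p = 0.106) did not. The values are consistent with fetus-wide differences or with tissues of a fetus handled together, which the labels do not tell apart.

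Other splits of the libraries were drawn for each comparison with 0 calls, using the count at an unadjusted p under 0.05, a measure chosen once those zero counts were known. As many miRNAs as in the real split came in 7 of 35 splits in kidney (33 miRNAs, highest other 42), 10 of 100 for liver ART against control (46, highest other 75) and 3 of 35 in skeletal muscle (58, highest other 61), so chance was not excluded there. In tongue 31 of 100 splits did so for LOS (25 miRNAs, highest other 85) and 48 of 100 for the sex by LOS term (20, highest other 99). Chance was not excluded for these either. The highest splits had several times the real count, which can point to a structure of the tongue libraries, but the other splits had medians of 17 and 19 miRNAs and such a structure was not tested. For sex in tongue 3 of 100 splits gave as many (62, highest other 98), a share under 0.05, although 0 miRNAs passed in edgeR, DESeq2 or limma-voom.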
